A study of Octopus bimaculoides with 4 samples.

How the data were processed

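Gene expression was measured in single cells of the optic lobe, the part of the brain behind the eye, of the octopus Octopus bimaculoides. Per the labels' protocols, lobes were dissected on ice and dissociated with papain. The suspension passed a 40 µm strainer, was brought to 2000 cells per microlitre and was loaded on a 10x Chromium with version 3 chemistry, aiming at 10000 cells. The libraries of both biological replicates were prepared on the same day and amplified with 11 PCR cycles. Each library was sequenced on a NextSeq and a HiSeq. The series therefore lists 4 samples, and the sample descriptions give the same matrix for both runs of a replicate, so that n = 2.

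The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.2, per the file headers and the submitters' processing notes. The matrices hold whole numbers for 18932 features and 6794880 barcodes each, so that empty droplets had not been removed. The genome build and the gene annotation are not given in the sources used here. Whether a matrix holds the reads of both the NextSeq and the HiSeq run or of 1 of them is not given either.

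Of the 18932 features, 18896 were nuclear genes that the files give only by an identifier, and 0 of these matched a name in the reference gene table. The other 36 were mitochondrial features, all matched by locus tag: 12 protein-coding genes, 2 rRNAs and 22 tRNAs. Cytochrome b was not analysed here, since no feature carries its locus tag. Before the data were examined, lists had been fixed for transmitter systems, neuropeptides, receptors, ion channels, transcription factors, adhesion genes and markers of neurons, immature cells, glia, vessels, hemocytes and photoreceptors. Without names, none of these could be measured, no cluster could be given a cell type, and the planned comparisons between immature and mature neurons, neurons and other cells, and transmitter classes could not be made. The list of mitochondrially encoded genes was the only one with names.

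Barcodes with at least 500 detected genes were kept as cells. Scrublet, run per replicate with an expected rate of 0.08, called 0 doublets and found no threshold in replicate 1, so the planned removal of doublets took no effect. Scores of 0.3 or more, held by 507 cells of replicate 1 and 438 of replicate 2, were removed in an alternative chosen after seeing the data. Free RNA was profiled per replicate in barcodes with 100 to 500 UMIs and fewer than 500 genes. Its subtraction removed, for every cell, the median UMIs of these barcodes in the proportions of their summed profile. Such barcodes can include small or damaged cells.

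Counts were scaled to 10000 per cell and log-transformed. Both replicates were clustered together on 2000 variable nuclear genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1. Mitochondrial genes were left out, so that clusters were not defined by the genes tested between them. Clusters were grouped into 4 branches by Ward linkage on centred log2 CPM with a pseudocount of 1. This grouping was chosen after seeing the data, from 16 combinations of linkage and number of branches. It kept 93.2 to 98.9% of cells in the same branch over 14 other clusterings, the highest minimum among the groupings into 3 or more branches. These 14 included the clusterings on single gene sets described below. Average linkage into 2 branches kept 94.3 to 99.2%.

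UMIs were summed per branch or cluster and replicate, for clusters with at least 20 cells in each replicate. Each branch or cluster was compared with the mean of the others by edgeR's quasi-likelihood test, with TMM scaling, filterByExpr at its minimum of 10 counts and the replicate as a block. Every library holds every cluster, so the block is a pairing within a library. All branches, or all clusters, were fitted together, because the sums of a single cluster cannot give a dispersion alone. The SE and p of edgeR thus rest on a spread pooled over all sums of both libraries. The adjusted p is Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. A count adjusted over the list alone is given beside it. The list was tested with camera at a preset correlation of 0.01 and with an estimated correlation. The rule for named genes, fixed before the data were examined, took from each tested list up to 4 genes with the largest and up to 4 with the smallest fold change among those that passed with the same sign in both replicates, and at most 2 identifiers that were higher and 2 that were lower where features have no names. Where 5 or fewer members of the list passed in a branch, all are named.

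Nuclear genes that make clusters also differ between them by construction. They were therefore split at random into sets A and B of like size. Cells were clustered on set A alone and the genes of set B were tested between the resulting branches and clusters, and the reverse. This scheme was chosen after seeing the data.

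The edgeR step was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Between branches, 63 to 89% of 2-fold changes and 86 to 97% of 4-fold changes were recovered among 12471 to 12489 genes, and 8.02 to 12.7% of the calls were false. In the held-out comparison the recovered shares were 62 to 85% and 89 to 99% among 6256 to 6270 genes, with 5.03 to 12.9% false. For cluster 5 they were 97 and 99% among 10807 genes, with 8.84% false. For cluster 21, a small cluster, they were 50 and 74% among 10798 genes, with 6.06% false. False calls were thus more frequent than the threshold of 0.05 allows. In the data 42.1 to 67.4% of held-out genes passed per branch, far more than were changed here, so these rates may not hold there. The measure of shared variance gave 84.9 where 84.3% was simulated.

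Shares of cells carry exact 95% Clopper-Pearson intervals, which cover counting error only. Means over replicates carry the SD of n = 2. The alternatives were a minimum of 800 genes, a UMI minimum at 10% of the 99th percentile of the 10000 largest barcodes, no doublet removal, Leiden resolutions 0.5 and 2, 50 components and 4000 variable genes. Others kept mitochondrial genes in the clustering, left out each replicate or the barcodes shared by both libraries, dropped the replicate block, changed the filter on low counts, or used DESeq2's size factors or Wald test. Software was Python 3.11.15, scanpy 1.11.5, python-igraph 0.11.9, scipy 1.17.1, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.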

Results

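Single-cell RNA-seq was made from the optic lobes of Octopus bimaculoides, in 1 group of 2 biological replicates. The study asks which cell types make up the visual system of this animal. The matrices held 125459929 UMIs in replicate 1 and 73467612 in replicate 2. With a minimum of 500 detected genes, 21791 cells were kept in replicate 1 and 16903 in replicate 2, together 38694. These cells held 82.5% of all UMIs of replicate 1 and 82.4% of those of replicate 2. The median cell had 3207 UMIs and 1641 genes in replicate 1, and 2452 UMIs and 1383 genes in replicate 2.

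The first comparison asked how the cells fall into classes and whether both replicates hold them in like shares. The cells formed 32 clusters, which Ward linkage placed in 4 branches. Branch 1 held 24 clusters and 64.1 ± 0.772% of the cells (SD, n = 2). Branch 2 held 4 clusters (1, 6, 8 and 11) and 27.7 ± 2.79%. Branch 3 held clusters 12 and 16 and 5.33 ± 3.09%, and branch 4 held clusters 18 and 20 and 2.85 ± 1.07%. These shares depend on the rule for cells: a UMI minimum at 10% of the 99th percentile gave 74.9, 14.1, 8.87 and 2.13% for branches 1 to 4. The largest cluster, cluster 1, took 13.6% of replicate 1 (95% interval 13.2 to 14.1) and 16.1% of replicate 2 (15.6 to 16.7).

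Cluster shares differed by less than 1.5-fold between replicates in 28 of the 32 clusters. The other 4 were clusters 6, 12, 16 and 18. Cluster 6 took 9.19% of replicate 1 (95% interval 8.81 to 9.58) and 1.82% of replicate 2 (1.63 to 2.04). Cluster 12 took 1.64% and 4.41%, cluster 16 took 1.51% and 3.10%, and cluster 18 took 2.14% and 0.858%. Branch 3 as a whole was 2.39-fold larger in replicate 2, with 3.15% of the cells of replicate 1 (2.92 to 3.39) and 7.51% of those of replicate 2 (7.12 to 7.92). No share was tested between groups, since there is only 1 group.

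**Figure D1:**
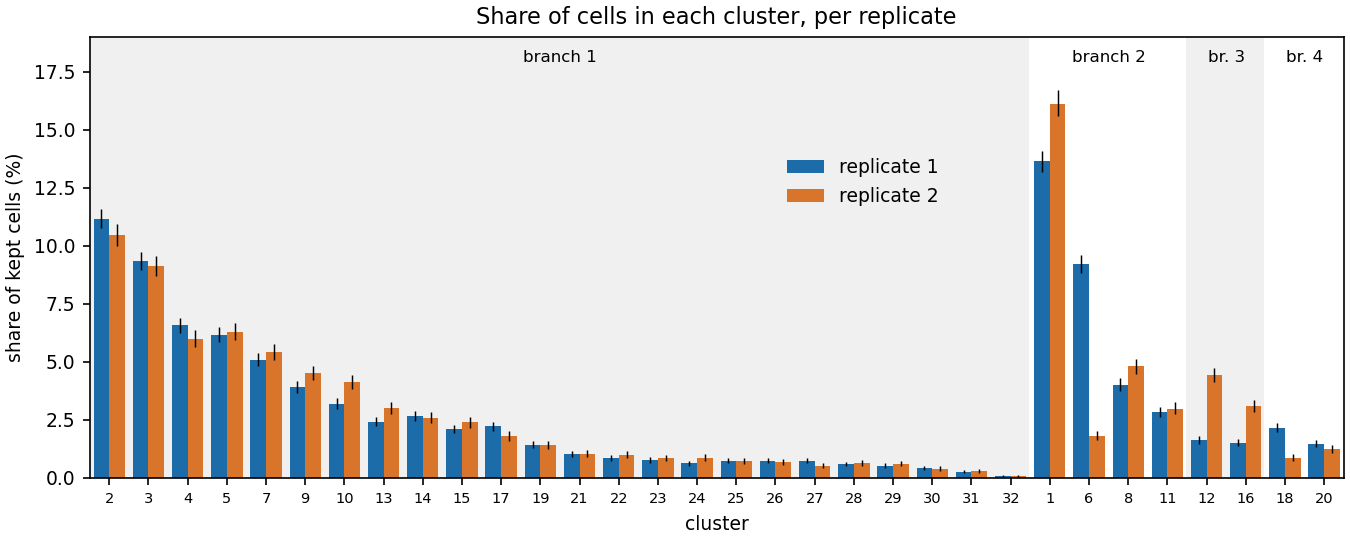
Share of kept cells in percent (vertical axis) for each of the 32 clusters (horizontal axis, ordered by branch), in replicate 1 (blue) and replicate 2 (orange), with exact 95% binomial intervals. Cluster 6 takes 9.19% of replicate 1 and 1.82% of replicate 2, and clusters 12 and 16 take larger shares of replicate 2.

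The branches differed in how much RNA their cells held and in how many genes it was spread over. Branch 3 cells were the deepest, with a median of 7970 ± 2816 UMIs (mean and SD of the replicate medians, n = 2), against 3430 ± 883 in branch 1, 1754 ± 94.0 in branch 2 and 2229 ± 27.6 in branch 4. Thinned to 1000 UMIs per cell, branch 3 cells showed a median of 556.8 ± 0.354 genes. Branch 1 cells showed 716.0 ± 4.24, branch 2 cells 711.0 ± 9.90 and branch 4 cells 675.3 ± 11.0 at the same depth. The gaps in gene number between branch 3 and the others exceeded the spread between replicates. In branch 3 the 10 most abundant genes took 16.6 ± 3.23% of the UMIs, against 6.21 ± 0.222% in branch 1, 7.19 ± 0.517% in branch 2 and 6.76 ± 0.867% in branch 4. Cells with fewer than 1000 UMIs could not be thinned and were left out of the gene numbers: 1416 and 797 cells of branch 2 in replicates 1 and 2, and at most 615 of any other branch.

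The second comparison asked how the mitochondrially encoded genes, which serve the respiratory chain and ATP synthesis, vary between cell classes. They took 3.73% of the UMIs of all cells in replicate 1 and 2.94% in replicate 2. The share was lowest in branch 3 (2.13 ± 0.272%, SD, n = 2), followed by branch 1 (3.34 ± 0.460%), branch 4 (4.17 ± 1.07%) and branch 2 (4.37 ± 0.703%). The order of branches 2 and 4 lay within the spread between replicates. Over single clusters it ran from 1.89 ± 0.274% in cluster 12 to 6.49 ± 0.94% in cluster 6, a 3.43-fold range. Cluster 12 was not the lowest in the tests with TMM scaling below. There the median log2 fold change of mitochondrial genes was -0.22 in cluster 12 and -0.87 in cluster 30. In cluster 12 the 10 most abundant genes took 22.2 ± 1.01% of the UMIs. Cluster 18 (6.19 ± 0.611%) and cluster 13 (5.96 ± 1.43%) were next to cluster 6 at the upper end. With free RNA subtracted the range was 3.47-fold, from 1.68 ± 0.222% in cluster 12 to 5.84 ± 0.581% in cluster 18, and cluster 6 came after cluster 13 (5.65 ± 1.52%) with 5.55 ± 0.722%. Replicate 1 had the higher share in each of the 32 clusters, by 1.21-fold at the median.

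Most mitochondrial UMIs came from subunits of cytochrome c oxidase: COX2 (gene-A3275_gp10) made 26.6 ± 11.2% of them, COX3 (gene-A3275_gp01) 25.01 ± 6.11% and COX1 (gene-A3275_gp11) 18.0 ± 7.95% (SD, n = 2). ND2 (gene-A3275_gp12), a subunit of NADH dehydrogenase, made 13.4 ± 7.93%. The ATP synthase subunits ATP6 (gene-A3275_gp08) and ATP8 (gene-A3275_gp09) made 6.78 ± 3.13% and 3.79 ± 3.36%. ND4 had 9 UMIs in replicate 1 and 24 in replicate 2, and ND1 had 1 and 0. ND4L and all 22 tRNAs had 0 UMIs, which allows up to 0.0290 CPM in replicate 1 and 0.0496 CPM in replicate 2 (3 counts per replicate). The list tested below thus had 11 measured members.

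**Figure D2:**
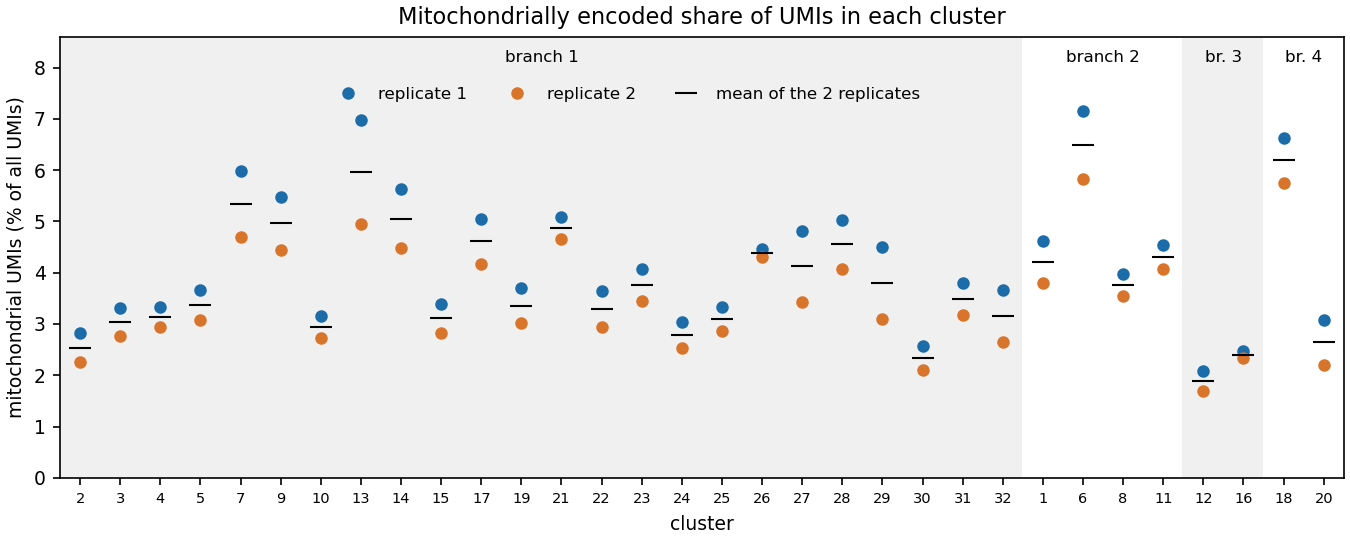
Percent of UMIs from mitochondrially encoded genes (vertical axis) in each cluster (horizontal axis, ordered by branch), in replicate 1 (blue), replicate 2 (orange) and as their mean (black dash). Cluster means run from 1.89% in cluster 12 to 6.49% in cluster 6, and replicate 1 lies above replicate 2 in each of the 32 clusters.

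Between branches, 5 of the 11 mitochondrial genes were higher in branch 2 than in the mean of the other branches, and 5 were lower in branch 3 (edgeR, 13014 genes tested). In branch 2 these were ATP8 (log2 fold change 0.54 ± 0.13, SE, edgeR adjusted p = 0.0040), ATP6 (0.45 ± 0.11, edgeR adjusted p = 0.0048), ND2 (0.34 ± 0.10, edgeR adjusted p = 0.0143), COX2 (0.28 ± 0.11, edgeR adjusted p = 0.0497) and the rRNA gene-A3275_gr02 (0.65 ± 0.16, edgeR adjusted p = 0.00475). In branch 3 the lower genes were gene-A3275_gr02 (-1.08 ± 0.18, edgeR adjusted p = 0.000344), ATP6 (-0.65 ± 0.12, edgeR adjusted p = 0.000608), ATP8 (-0.46 ± 0.14, edgeR adjusted p = 0.0122), COX1 (-0.40 ± 0.12, edgeR adjusted p = 0.0120) and COX2 (-0.29 ± 0.12, edgeR adjusted p = 0.0472). Each had the same sign in both replicates, taken against the other branches' mean log2 CPM without TMM. On that scale genes that did not pass could share the sign too. COX3 in branch 3 was -0.78 in replicate 1 and -0.69 in replicate 2, beside -0.11 with TMM. The shared sign is thus weak support. In branch 4, gene-A3275_gr02 alone was higher (0.65 ± 0.17, edgeR adjusted p = 0.0140). Clusters of that branch differed: it was 1.28 ± 0.13 in cluster 18 (edgeR adjusted p = 2.98e-11) and -0.22 ± 0.15 in cluster 20 (edgeR adjusted p = 0.419). Their mitochondrial shares were 6.19 and 2.65%. In branch 1 the other rRNA, gene-A3275_gr01, alone was lower (-0.68 ± 0.21, edgeR adjusted p = 0.0160). This call rested on few UMIs. In replicates 1 and 2 the gene had 199 and 115 in branch 1, 78 and 43 in branch 2, 21 and 25 in branch 3, and 17 and 7 in branch 4. Adjusted over the list alone, 0, 4, 4 and 1 genes passed in branches 1, 2, 3 and 4. Such calls were no trait of the list. Of held-out nuclear genes, 60.8, 59.6, 67.4 and 42.1% passed in branches 1 to 4 drawn from gene set A. Without cluster 6, ATP8 (0.46 ± 0.13, edgeR adjusted p = 0.0104), ATP6 (0.36 ± 0.11, edgeR adjusted p = 0.0163), gene-A3275_gr02 (0.45 ± 0.16, edgeR adjusted p = 0.0313) and ND2 (0.29 ± 0.11, edgeR adjusted p = 0.0340) still passed in branch 2 over all genes, and 0 over the list alone. With free RNA subtracted, 0 passed there over the list alone, and 3 had an unadjusted p under 0.05 in edgeR. The calls of COX2 held least: in branch 2 it no longer passed in 13 of 16 alternatives, and in branch 3 it kept its call in 7 of 16.

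The median gene of all 13014 had a log2 fold change of -0.17 in branch 3 and -0.04 in branch 2, beside -0.29 and 0.28 for the median mitochondrial gene. DESeq2's size factors moved the median of all genes by -0.14 in branch 1 and 0.11 in branch 3, where COX2 no longer passed (-0.18, edgeR adjusted p = 0.111). ND5, which had not passed in branch 3 (0.36 ± 0.17), then passed as higher there (0.46 ± 0.15, SE, edgeR adjusted p = 0.0240). Its sign differed between replicates. Against the other branches' mean log2 CPM without TMM it was -0.63 in replicate 1 and 0.04 in replicate 2. With TMM it also passed as higher with 4000 variable genes (0.43 ± 0.17, edgeR adjusted p = 0.0407), with a minimum of 800 genes (0.44 ± 0.17, edgeR adjusted p = 0.0384) and with the UMI minimum (0.64 ± 0.16, edgeR adjusted p = 0.00494). Under the UMI minimum only ATP8 of the 5 genes still passed in branch 2 (0.29 ± 0.11, edgeR adjusted p = 0.0383), where the list's median turned to -0.06. Only gene-A3275_gr02 and ATP6 then still passed as lower in branch 3, and gene-A3275_gr02 no longer passed in branch 4 (0.04 ± 0.20, edgeR adjusted p = 0.913). As a list, the 11 genes did not pass camera's test against other genes in any branch. With the preset correlation p was 0.464, 0.166, 0.221 and 0.846 for branches 1 to 4, and with an estimated correlation p = 0.817, 0.652, 0.702 and 0.951. In branch 4 the test pointed down while the list's median fold change was 0.09. With free RNA subtracted, only ATP8 of the 5 genes still passed in branch 2 (0.45, edgeR adjusted p = 0.0213). ATP6 (0.30) and ND2 (0.29) then each had an edgeR adjusted p of 0.0513. COX2 (0.15) and gene-A3275_gr02 (0.37) had edgeR adjusted p = 0.316 and 0.117. In branch 3, 4 of the 11 genes passed after this subtraction over all genes, and 2 over the list alone. The list's median there was -0.22, close to the -0.19 of the median gene of all. With 4000 variable genes 0 of the 11 passed in branch 2. Without the replicate block none of the 11 genes passed in any of the 4 branches, with 1, 0, 0 and 1 at an unadjusted p under 0.05. Leaving the block out counts the difference between replicates as error: the SE of COX3 in branch 1 rose from 0.11 to 0.52. The list's median was then 0.29 in branch 2 and -0.35 in branch 3.

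Between single clusters the mitochondrial genes differed more widely. Of 341 tests of 11 genes in 31 clusters, 216 passed in edgeR, 103 of them higher and 113 lower, and 228 passed adjusted over the list alone. Genes of 1 cluster mostly moved together. All 11 were higher in cluster 6, with a median log2 fold change of 0.81, and 10 each were higher in cluster 18 (median 0.81), cluster 13 (0.74) and cluster 7 (0.57). All 11 were lower in cluster 2 (median -0.66), 10 in cluster 10 (-0.45), and 9 each in cluster 30 (-0.87) and cluster 20 (-0.61). In cluster 23, 0 genes passed in edgeR or in DESeq2's test, with 0 at an unadjusted p under 0.05.

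By gene, ATP8 passed in 28 of the 31 clusters, COX1 in 26, ND2 in 24 and COX3 and ATP6 in 23 each. COX1 was 0.84 ± 0.06 (log2, SE) higher in cluster 18 and 0.74 ± 0.06 higher in cluster 13 (edgeR adjusted p = 3.09e-15 and 4.41e-13). In cluster 30, COX1 was lower by -0.79 ± 0.08 and ATP8 by -0.98 ± 0.08 (edgeR adjusted p = 2.05e-11 and 4.06e-13). These SE and p rest on the spread pooled over all clusters of the same libraries. They do not measure how a single cluster would vary over further replicates. Of the 228 tests that passed over the list alone, 206 also passed with the same sign after free RNA was subtracted, and all 228 kept their sign with DESeq2's size factors. Without the replicate block, 6 of the 341 tests passed (1.76%), all with the same sign, and with a UMI minimum for cells 38.2% passed over the list alone.

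The third comparison asked whether the classes also differ in nuclear genes that took no part in defining them. With branches drawn from gene set A, 2148 of 6544 set B genes were higher and 1829 lower in branch 1 than in the mean of the other branches (edgeR). In branch 2, 1808 were higher and 2089 lower, in branch 3, 2091 and 2321, and in branch 4, 1379 and 1375. At over 2-fold, 1318 genes were higher and 1446 lower in branch 3, and 576 were higher and 1337 lower in branch 2. With the sets exchanged, 3830, 3821, 4493 and 2408 of 6490 genes passed in branches 1 to 4. Without the replicate block, 2309, 1857, 2825 and 1335 set B genes passed, with 1010 higher and 325 lower in branch 4. The balance of directions turned with DESeq2's size factors, which gave 2005 higher and 2081 lower in branch 1 and 2224 and 2176 in branch 3.

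Branch 3 had the most differing genes, 4412, and its most changed identifiers carry no names in the files. By edgeR's fold change, which takes the mean of the other branches' log2 levels, the highest were obimac_0010750 (log2 11.02 ± 0.22, SE, edgeR adjusted p = 6.54e-10) and obimac_0007084 (10.95 ± 0.22, edgeR adjusted p = 7.08e-10). In mean CPM the first reached 121.6 in branch 3 against 0.230 in the others together, a smaller ratio of 529, and the other reached 87.4 against 0.126, a ratio of 693. At the other end, obimac_0032087 had 0 UMIs in branch 3 and 10.3 CPM in the others, at least 72.4-fold lower, and obimac_0028665 had 0 UMIs against 2.23 CPM, at least 15.7-fold lower (against 3 counts over the branch's UMIs, or 0.142 CPM).

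Single clusters differed in held-out genes as well. Over the 30 clusters drawn from set A, 722 to 4159 of 5964 set B genes passed per cluster, with a median of 1666.5 (edgeR). Pooled over branches, clusters of 1 branch resembled each other more than clusters of other branches in these genes. Across genes, the median r was 0.889 for 207 pairs within a branch and 0.756 for 228 pairs of different branches. With the sets exchanged these were 0.887 and 0.795. Most clusters lie in branch 1 (24 of 32 in the main clustering). The median within a branch thus mainly describes branch 1 and says little of branches with few clusters. Genes are not independent replicates, and no p was computed for these correlations. Clusterings on the separate sets had an adjusted Rand index of 0.671 with each other and placed 95.3% of cells in the same branch. The 95.3% is no separate support for the branches, since their grouping was chosen for stability over clusterings that included these. Of the 32 clusters, 18 had a counterpart with a Jaccard index over 0.5 in both sets' clusterings.

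The fourth comparison asked how far the replicates agreed within each class. Pearson's r across genes between the replicates' summed profiles had a median of 0.917 over clusters, from 0.565 to 0.958, and Spearman's rho a median of 0.926. The lowest r was that of cluster 32, with 17 and 10 cells in replicates 1 and 2. Cluster 31, with 59 and 47 cells, had 0.731, and the highest r was that of cluster 2, with 2432 and 1765 cells. The range thus goes with the number of cells summed. Over the 11 measured mitochondrial genes alone the median r of the 32 clusters was 0.933, from 0.902 to 0.9404. Genes are not independent replicates here either. Despite these values, single mitochondrial genes differed between replicates in opposite directions. ND5 was 4.64-fold and ATP8 3.45-fold higher in replicate 2, while ND3 was 2.80-fold, ATP6 2.49-fold and COX2 2.34-fold higher in replicate 1. ND2 (1.92-fold) and COX1 (1.505-fold) were higher in replicate 2, and COX3 (1.80-fold) in replicate 1. All 8 genes kept that direction in each of the 31 clusters. The 8 were taken by a minimum of UMIs, and their differences were examined after their values were seen.

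**Figure D3:**
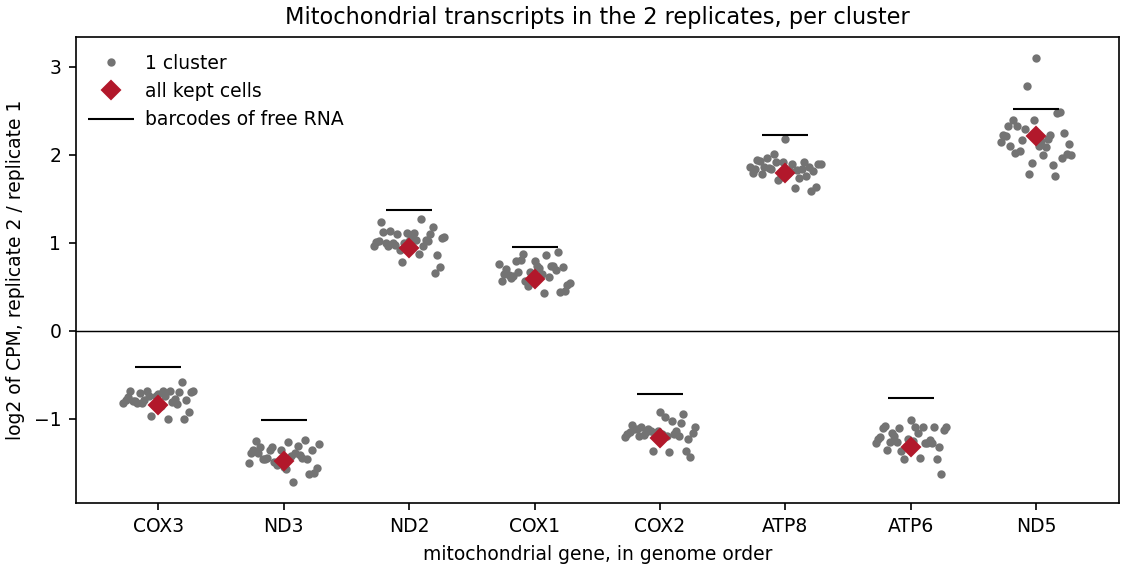
Log2 ratio of CPM in replicate 2 to replicate 1 (vertical axis) for 8 mitochondrial genes (horizontal axis), in each of 31 clusters (grey points), in all kept cells (red diamonds) and in barcodes of free RNA (black dashes). The 31 clusters lie on 1 side of 0 for each gene, around -1.48 for ND3 and 2.21 for ND5 in all kept cells.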

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

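All tests of causes in this part were chosen after the results they address had been seen. Barcodes with 100 to 500 UMIs and fewer than 500 genes, which served only as the profile of free RNA, held mitochondrial RNA: 8.99% of their UMIs in replicate 1 and 9.41% in replicate 2, above the 3.73% and 2.94% of cells and above the 6.49% of the cluster with the largest share. The profiles of these barcodes had an r of 0.982 between replicates, across genes. These shares drew attention because such barcodes were not counted as cells.

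Mitochondrial genes differed between replicates in opposite directions, with 248 of 248 pairs of gene and cluster on the side of the pooled value. Different cell makeup would give ratios near 0 within clusters, but their mean absolute log2 ratio was 1.29, and makeup alone gave 0.06. Free RNA would give a smaller difference in branch 3, whose cells held an estimated 2.41% of free RNA against 13.8% in branch 2, yet the difference in branch 3 was 104.2% of that in branch 2. An effect on single genes that runs through a whole library remains open: nuclear genes showed it too, since 87.1% of the variance of 5161 genes' log2 ratios was shared by 14 clusters. It may come from the animals, the libraries or the sequencing, which cannot be told apart with 1 library per replicate, and no biological explanation was tested.

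Cluster 6 took 9.19% of replicate 1 and 1.82% of replicate 2. Whether its barcodes hold mostly free RNA remains open: its nuclear profile correlated more strongly with free RNA (0.987 and 0.953) than with the nearest other cluster (0.963 and 0.944), by 0.00918 in the replicate with the smaller gap. That cluster, 10 in both replicates, had a like r with free RNA (0.957 and 0.952). It lies in branch 1, while cluster 6 was placed in branch 2. Free RNA was estimated at 37.2 and 17.8% of the UMIs of cluster 6, which cannot decide the question. The estimate took the same 382 and 196 UMIs for every cell of replicates 1 and 2, whatever its own content. Cells of cluster 6 lay near the minimum for cells, with medians of 890 and 907.5 UMIs. Of them, 12.7 and 18.8% had 800 genes. Small or damaged cells may give the same values, and no biological explanation was tested.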

How the results depend on the processing

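The alternatives for cells, shares and correlations were planned, except the doublet scores, gene sets and free RNA, and so were camera's estimated correlation and its test without the block. Other alternatives for mitochondrial and held-out genes were chosen after seeing the data. Of 573 alternative values over 23 settings, 459 kept their direction and side of the threshold (tests), moved by less than the SD over replicates or clusters (other values) or stayed within 1.5-fold (counts and percent of tests). The count includes the setting without doublet removal, whose values are the same by construction, since 0 doublets had been called. The cause was not tested for any change given here.

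The UMI minimum at 10% of the 99th percentile kept 10398 and 9527 cells, with medians of 6167 and 4046 UMIs, and gave branch shares of 74.9% (branch 1), 14.1% (branch 2) and 8.87% (branch 3). Mitochondrial shares were then 3.18% in branch 2 and 3.09% in branch 4, with 0, 1, 3 and 2 mitochondrial genes passing in branches 1 to 4, and 38.2% of cluster tests. These calls were partly other ones: in branch 3 ATP8, COX1 and COX2 were lost and ND5 was higher, and in branch 4 gr02 was lost and ND2 (-0.33, edgeR adjusted p = 0.0219) and ND5 (-0.54, edgeR adjusted p = 0.0341) were lower. The list's median in branch 2 turned to -0.06, and COX2 in branch 3 to 0.0523 (edgeR adjusted p = 0.663). A minimum of 800 genes gave 69.8% in branch 1, 22.2% in branch 2 and 0 mitochondrial genes in branch 1. Leiden resolution 2 gave 54 clusters, 70.1% in branch 1, 21.7% in branch 2 and 0 genes in branch 1. Resolution 0.5 gave 3 genes in branch 4. With 4000 variable genes, branches 1 and 2 took 59.4 and 32.7%, and 0, 0 and 3 genes passed in branches 1, 2 and 4. Without doublet scores of 0.3 or more, branch 1 took 63.0%, and 3 genes passed in branch 2. With mitochondrial genes in the clustering it took 62.8%. Clustering on gene set A alone gave 61.0 and 31.2% for branches 1 and 2, and on set B 59.1 and 32.8%. Leaving out 1 replicate gave 60.7 to 64.5% in branch 1, 26.0 to 32.6% in branch 2, and mitochondrial shares of 3.59 to 4.44% in branch 2.

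Free RNA subtraction gave a mitochondrial share of 3.62% in branch 2, with 1 gene passing there and 2 in branch 4. Without the replicate block, 0 mitochondrial genes passed in each branch, 1.76% of cluster tests passed, and 2309, 1857, 2825 and 1335 held-out genes passed in branches 1 to 4. DESeq2's Wald test gave 3 genes in branch 1 and 2 in branch 4, and edgeR with DESeq2's size factors gave 2 in branch 1. With CPM over 10 in 2 sums, 0 passed in branch 1. With no filter beyond 1 count, 2 passed in branch 4, and camera's p for branch 2 fell to 0.0209 (0.402 with an estimated correlation). Where 0 genes passed in a branch, 0 or 1 had an unadjusted p under 0.05 in edgeR. The direction of camera's test in branch 4 turned up under 8 settings, and none of these passed. Camera's p on the edgeR counts was then 0.669 (doublet scores), 0.653 (resolution 0.5), 0.982 (resolution 2), 0.962 (50 components), 0.400 (4000 variable genes), 0.894 (mitochondrial genes in the clustering), 0.925 (without cluster 6) and 0.713 (no filter). The median r between replicates was 0.934 over the 11 measured genes of the list only, in the 31 tested clusters. The held-out identifiers kept their direction and call in all 31 alternatives, and the 12 mitochondrial calls in branches kept theirs in 140 alternatives, kept only their direction in 50 and reversed in 1, COX2 above. COX2 lost its call in 13 of 16 in branch 2. In branch 3 it lost its call in 8 that kept the direction and in the 1 that reversed. The 8 replicate ratios kept their direction in all 40.

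The alternatives planned for transmitter genes, immature and mature neurons, neurons and other cells, transmitter classes and co-expression were not run, since the features have no names. Tests without 1 replicate were not run for genes, since they leave no residual degrees of freedom. Cluster 32, with 17 and 10 cells in the replicates, fell below the minimum of 20 and was not tested.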

Other observations

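The tests in this part on neighbouring identifiers were stated before their results were seen, and the other values were chosen after seeing the data. Between replicates, the identifier obimac_0013596 differed in every cluster tested: it had 392.1 CPM in replicate 1 and 8.54 CPM in replicate 2, with the same direction in all 31 clusters, and 743.9 and 18.9 CPM in barcodes of free RNA. The identifier was chosen after its values were seen. Of 3722 nuclear genes over 50 CPM, 533 differed by over 2-fold and 59 by over 4-fold between replicates. Among cell barcodes, 101 occurred in both replicates, where 54.2 would by chance.

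Nuclear genes whose identifiers follow each other had profiles across the 31 clusters that were more alike than those of random pairs, though weakly. The median r of 4142 pairs, each with 1 gene from either replicate, was 0.146, above the 0.0558 to 0.0794 of 100 random pairings, and 5.00% of pairs had an r over 0.7 against 0.979% at random. It fell to 0.108 at a distance of 2, to 0.0960 at 3 and to 0.0809 at 5, where 15.8% of the excess was left, and was 0.0807 at 10, with 15.5% left. This is consistent with identifiers that follow the order of genes on chromosomes, which the files do not state. Reads shared by adjacent near-identical gene models may contribute, and this cannot be told apart from shared regulation, since the remaining excess lay between the bounds set for either and the sources used here hold no sequences of these genes. No biological explanation was tested.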
